A study of Mus musculus with 6 samples.

How the data were processed

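Each array held 1 sample of total RNA, labelled with Cy3 and hybridised in 1 colour. Per the file headers, the authors' scanner images were quantified with Agilent Feature Extraction 10.7.3.1, which the submitters' processing notes also name. The deposited files hold spot intensity on a linear scale, and per the file headers the processed intensity had the background subtracted, was detrended within the array and had dim spots replaced by a surrogate value. No normalization between arrays had been applied to these deposited intensities. Per the file headers, all 6 arrays lay on 1 slide and were scanned in 1 run, so no slide or scan could be tested as a batch. Probe coordinates in the files were on mm9. No spot was saturated (0 on the 6 arrays).

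The processed intensity was turned to log2 and the 75th percentile of each array over gene probes was subtracted, whereas the deposited values themselves were not on a log2 scale. Of 62976 spots, 59305 were gene probes, and between 101 and 121 of these per array were left out because the files marked them as outliers. Repeated spots were averaged, which gave 55680 probes. Names came from the accession for 27228 probes, from the symbol for 3586 and from a unique synonym for 565, through RefSeq genes of assembly GRCm38.p6 used for names only. A further 8107 probes kept the name in the file, and 16194 were lincRNA probes. A gene was represented by its probe with the highest mean over the 6 arrays, which gave 34740 genes, 11199 of them with more than 1 probe. Levels of different probes were never set against each other. Among the other probes of genes past the rule, 83.6%, 85.2% and 78.5% went the same way, and 42.2%, 41.1% and 33.6% were also past 2-fold, for KO against WT in macrophages without TNF, with TNF and in neutrophils.

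With 1 array per group, no test between genotypes within a condition was possible, and the number of arrays limits the precision. A model of genotype across the conditions, which would take the differences between conditions as its error, was not fitted, so no p-value is given. A gene counted as different when its log2 difference was at least 1 in size and its probe was well above background, by the files' own mark, on the brighter array. Where the dimmer array was not well above background, a bound was used. It set the brighter signal against the higher of the probe's own signal and that array's lowest signal well above background, had to reach 2-fold, and is given as "at least". For the difference between the TNF differences, the probe had to be well above background on all 4 macrophage arrays. The spread between spots of 1 probe within an array had a median SD of 0.07 on the log2 scale, and the log2 differences of the 8 spike-in probes had SDs from 0.18 to 0.80. Both describe technical scatter only, not that between mice. Before scaling, the mean spike-in differences, KO minus WT, were 0.27 and 0.42 in macrophages without and with TNF and 0.37 in neutrophils. No setting scaled the arrays to the spike-ins, which would lower the KO-minus-WT values.

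Gene lists were described by the median log2 difference of their measured members and its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. A list was called apart below percentile 2.5 or above 97.5, as a description of these arrays. The 19 lists fixed before the data were examined covered CXC and CC chemokines, chemoattractant receptors, inflammatory cytokines, NF-kB and TNF signalling, IL-6 and STAT signalling, interferon-stimulated genes, apoptosis, classical and alternative activation, iron and STEAP genes, oxidative burst and antioxidant genes, adhesion and matrix degradation, antigen presentation, cell cycle, lipid and cholesterol, immediate early and stress genes, housekeeping genes and the neighbours of Steap4. A further 15 marker lists covered macrophages, resident peritoneal macrophages, mature neutrophils, neutrophil granule precursors, B, plasma, T, NK, dendritic and mast cells with basophils, monocytes, eosinophils, erythroid cells, platelets, and mesothelial cells with fibroblasts. Of the 436 list members, 432 were on the array.

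The rule for named genes was also fixed beforehand. It named Steap4, Cxcl1, Cxcl2, Cxcr1, Cxcr2, Il6, Tnf and Il1b in every comparison. It also named the 8 largest increases and 8 largest decreases among brighter genes with an approved-style symbol, and the 2 largest in each direction of every list. Further list members are named where a count of members past the rule is given, and were chosen after their values were seen. How symbols were judged approved in style was tightened once after a first look at the names.

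The comparisons were KO against WT in each of the 3 conditions, TNF against no TNF label in each genotype, the difference between those, and WT neutrophils against WT macrophages. Groups came from the labels. Alternatives chosen beforehand were quantile normalization, scaling to the median of probes detected on all arrays, normexp background correction with an offset of 50 on the raw and local background intensity, and well above background on all arrays of a comparison. No filter on dim probes, the median over all probes of a gene, and removal of the intensity trend by loess with a span of 0.3 were the others. The calling steps were tested on simulated data built for KO against WT in macrophages without the TNF label, over 24096 genes. Of the genes given log2 changes of 1.5, 3, -1.5 and -3, 50 of 50 were recovered at each size, and 0 unchanged genes were called. The simulated noise had an SD of 0.0672 on the log2 scale, the scatter between spots within an array, so this checks that the steps work and gives no error rate for differences between arrays or mice. Of 200 simulated null lists, 12 fell outside the percentiles. The work used R 4.3.3 with limma 3.58.1 and data.table in version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Genome sequence was not used here, so strain variants under probes were not analysed here. The results of 3 list members are not reported here.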

Results

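Gene expression was measured on 6 single-colour Agilent mouse arrays, 1 for each of 6 groups. By label the mice were C57BL/6 and either wild type (WT) or deficient (KO) for TIARP. TIARP is the protein of Steap4, a membrane metalloreductase known for its induction by TNF in fat tissue. From each genotype there was 1 array of thioglycollate-elicited peritoneal macrophages without the TNF label, 1 of such macrophages with TNFα for 24 h and 1 of Ly6G+ neutrophils taken from spleen with magnetic beads. Whether an array holds RNA pooled from the 3 mice that the labels number is not given in the sources used here. Hours are given for the arrays with TNF only, so differences between arrays with and without TNF may also hold effects of time in culture. Each group had 1 array, so no difference had a replicate check, and genes were called higher or lower by a rule of size alone. The arrays' 75th percentile signals were 490, 410, 432 and 338 for WT and KO macrophages without and then with TNF, and 231 and 224 for WT and KO neutrophils. In the same order, 62.2%, 60.4%, 59.5%, 56.6%, 57.4% and 58.5% of probes were well above background.

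Steap4 itself was lower on all 3 KO arrays than on their WT counterparts, and passed the rule of size only in macrophages with TNF. Its log2 difference, KO minus WT, was -0.81 in macrophages without the TNF label and -0.39 in splenic neutrophils, neither past the rule. With TNF, Steap4 was not well above background on the KO array and was at least 3.00-fold lower there than on the WT array (log2 -1.59). That value was -0.32 and not past the rule with normexp background correction, and the probe was left out where signal well above background was required on all arrays. The linear signals of WT and KO were 175 and 83.1 without TNF, 49.2 and 12.8 with TNF, and 48.8 and 36.0 in neutrophils. The single probe, A_51_P143893, lies on chromosome 5 from 7981239 to 7981298 (mm9). The deleted part of the gene is not given in the sources used here, so this probe may lie outside it and does not check the labels. With TNF, Steap4 fell by 1.65 on the log2 scale in WT macrophages. In KO macrophages the difference was -2.42, a lower bound on the size of the fall. The 16 measured neighbours of Steap4 on chromosome 5 held 0 genes past the rule in macrophages without TNF, with a median log2 difference of -0.09. With TNF the list stood below random lists, with a median of -0.24 over 15 genes (percentile 0.56) and 0 past the rule, and lay inside the random range with the median over all probes of a gene. In neutrophils it was not apart (-0.08, percentile 27.0). Of these neighbours, Steap1 and Steap2 were at -0.52 and -0.45 without TNF and at -0.81 and -0.85 with TNF.

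**Figure D1:**
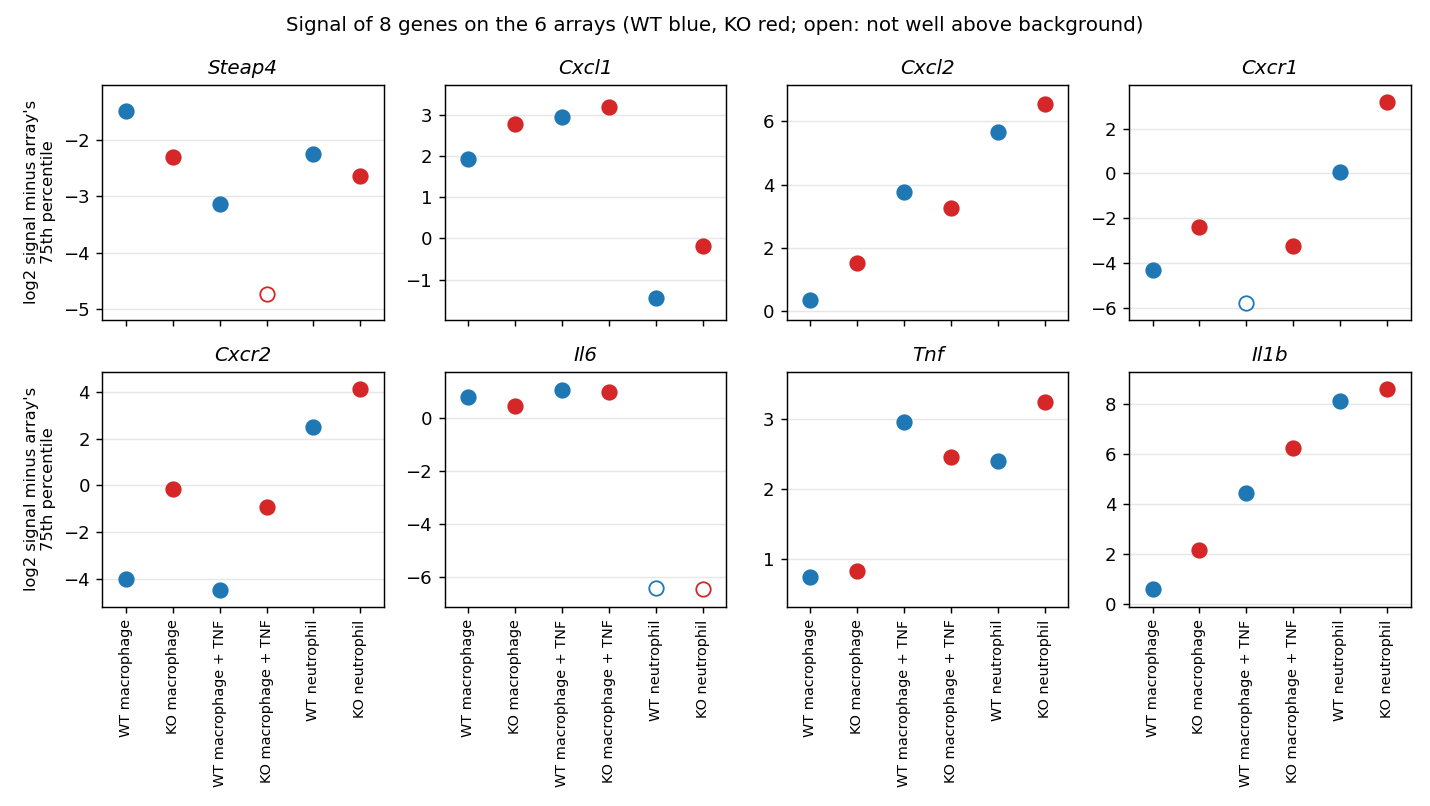
Signal of Steap4, Cxcl1, Cxcl2, Cxcr1, Cxcr2, Il6, Tnf and Il1b on each of the 6 arrays, as log2 signal minus the array's 75th percentile (vertical axis, separate scale for each gene), 1 point per array, WT blue and KO red, open where not well above background. Cxcr2 was higher on each KO array than on its WT counterpart, by log2 3.88, 3.53 and 1.63.

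The next comparison asked how KO macrophages differed from WT macrophages without the TNF label. Neutrophil genes were higher on the KO array. S100a9, a calcium-binding protein abundant in neutrophils, was 30.2-fold higher (log2 4.92), and Cxcr2, a receptor for neutrophil-attracting CXC chemokines, was 14.7-fold higher (log2 3.88). Of 10 measured mature neutrophil markers, 6 were higher, among them Ly6g, S100a8 and S100a9, with a median log2 difference of 1.99 that exceeded all 10000 random lists. Of 9 B-cell markers, 5 were higher, among them Cd79b and Ms4a1, with a median of 1.60, also at percentile 100. The mesothelial and fibroblast markers moved the other way, with 3 of 8 lower (Upk3b, Col1a1 and Col1a2), a median of -0.62 and percentile 0.

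Genes named by their size here and in the other comparisons were ranked among brighter genes only, those with a mean signal above the median, well above background on all arrays compared and with an approved-style symbol. Among these on that KO array, Zfp979, a zinc finger gene, was 43.8-fold higher (log2 5.45). Rarres2, which encodes the chemoattractant chemerin, was 10.2-fold higher (log2 3.36). The stefin genes Stfa2 and Cstdc5 (3.03 and 2.76), Ifitm1 (2.84), the adhesion molecule Nrcam (2.76) and the iron-binding granule protein Lcn2 (2.70) completed the 8 highest brighter genes. Stefin genes are near copies of each other, and their probes can pick up one another's RNA. The 8 lowest brighter genes were Akr1e1 (-2.83), Vps16 (-2.20), Mzt1 (-2.10), the ribosomal gene copy Rps4l (-1.59), Col6a3 (-1.59), Ap5s1 (-1.56), Mfge8 (-1.56) and Fndc1 (-1.56).

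Chemoattractant receptors were higher on the KO macrophage array without TNF, with 5 of 17 past the rule (Cxcr1, Cxcr2, Ccr6, Fpr2 and Ltb4r1), a median of 0.60 and percentile 100. Cxcr1, Cxcr2, Ccr6 and Fpr2, but not Ltb4r1, were also at least 2-fold higher on the WT neutrophil array than on the WT macrophage array without TNF. Cxcr1, which shares ligands with Cxcr2, was at 1.90. Among CXC chemokines, the B-cell attractant Cxcl13 (1.88) and the neutrophil attractant Cxcl2 (1.17) were higher and Cxcl12 was lower (-1.48), with a median of 0.44 over 12 genes and percentile 100. The CC chemokine list had a median of 0.25 (percentile 99.1) and 1 gene past the rule, the eosinophil attractant Ccl24 (1.69). Il1b was higher (1.55), as it was on the WT neutrophil array against WT macrophages. Cxcl1 (0.85), Tnf (0.08) and Il6 (-0.34) were not past the rule. The inflammatory cytokine list (median 0.07, percentile 63.1) and the NF-kB and TNF signalling list (0.17, percentile 97.48) were not apart from random lists.

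Both activation lists stood above the random lists in this comparison. Of 12 alternative activation genes, 4 were higher: Chil3 (2.33), the haemoglobin scavenger receptor Cd163 (at least 2.14), Clec10a and Ccl24 (median 0.27, percentile 99.9). Of 12 classical activation genes, Cd38 (1.54) and the acute-phase gene Saa3 (1.35) were higher (median 0.55, percentile 100). Chil3 is also made by neutrophil precursors and stood on that marker list too, where Prtn3, Ltf, Lcn2 and Chil3 were higher among 12 genes (median 0.26, percentile 98.0, inside the random range with quantile normalization). Interferon-stimulated genes had a median of 0.36 (percentile 100), with Ifi44 alone past the rule, 25.1-fold higher (log2 4.65). Antigen presentation genes had a median of 0.47 (percentile 100) with 0 of 14 past the rule. That list was also higher on the WT neutrophil array than on the WT macrophage array without TNF. The cell cycle list (-0.34) and the oxidative burst and antioxidant list (-0.14) stood below the random lists, both at percentile 0, with 0 genes past the rule.

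Among markers of further cell types in these macrophages, 3 of 9 T-cell markers were higher: Cd8b1 (1.95), Cd3g (1.30) and Cd3d (median 0.37, percentile 99). Of 5 mast cell and basophil markers, 3 were higher, namely Fcer1a (1.27), Cpa3 (1.15) and Tpsb2 (median 1.02, percentile 99.9). The monocyte list had F13a1 higher (1.41; median 0.61, percentile 99.97). General macrophage markers had a median of 0.24 (percentile 99.5) with 0 of 14 past the rule, and among resident peritoneal macrophage markers Timd4 (1.29) and Alox15 (1.09) were higher, in a list not apart from random lists (median 0.19, percentile 91.7). In all, 1006 genes were higher and 382 lower by at least 2-fold among 24654 tested. The counts were 305 higher and 345 lower once genes at least 2-fold higher on the WT neutrophil array than on the WT macrophage array with TNF were left out, a setting chosen after seeing the data. With normexp background correction the counts were 332 and 106.

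**Figure D2:**
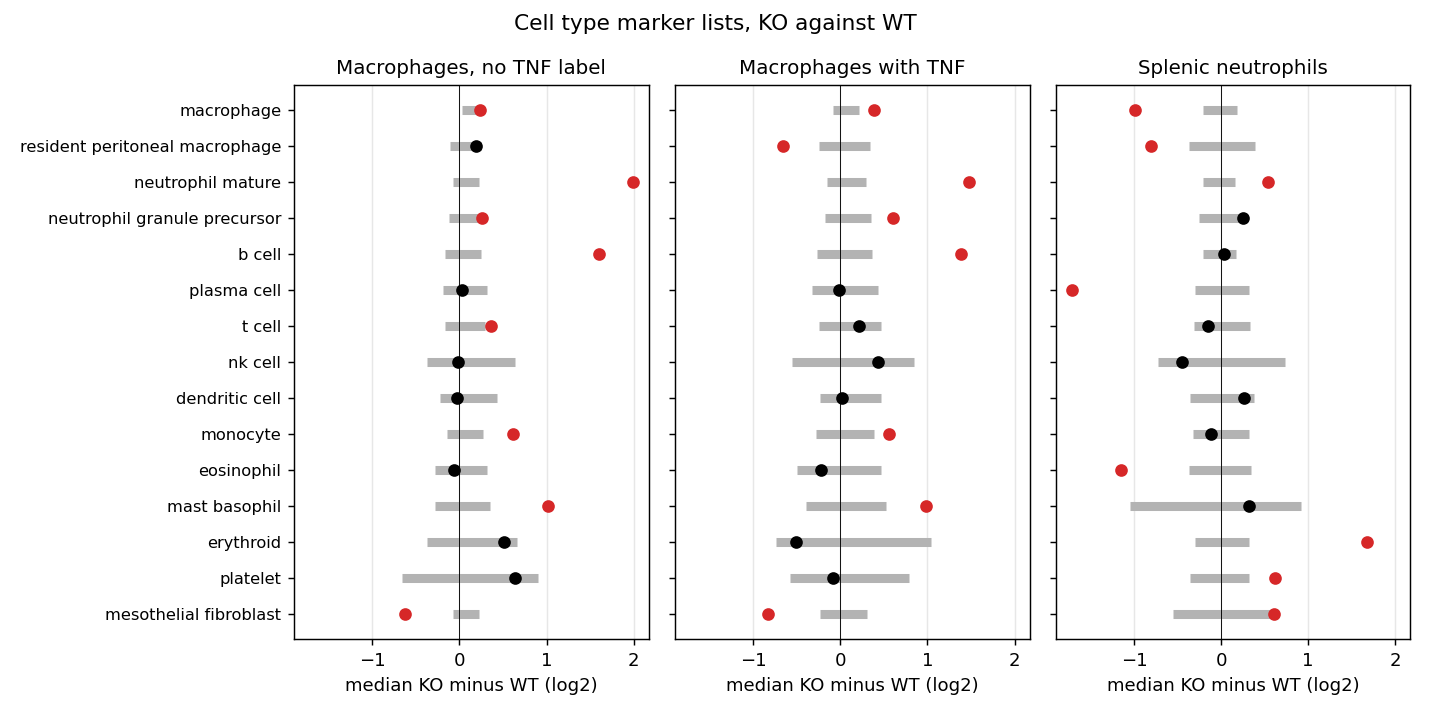
Median log2 difference, KO minus WT (horizontal axis), of 15 cell type marker lists (rows) in macrophages without the TNF label, macrophages with TNF and splenic neutrophils, as 1 point per list, red where outside the grey bar, which spans the inner percentiles of 10000 random lists within which a list was not called apart. The mature neutrophil list lies at 1.99, 1.47 and 0.54 in the 3 panels, and the plasma cell list at -1.71 in neutrophils.

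The same genotypes were compared in macrophages with TNF. Neutrophil and B-cell markers were again higher on the KO array, with 7 of 11 and 7 of 9 past the rule and medians of 1.47 and 1.38, both at percentile 100. S100a9 was 17.1-fold higher (log2 4.10), Cxcr2 was at 3.53 and Cd79b, a part of the B-cell antigen receptor, at 2.31. Interferon-stimulated genes were higher as a list, with 6 of 22 past the rule (Ifit3, Irf7, Mx1, Rsad2, Usp18 and Ifi44), a median of 0.77 and percentile 100. Ifi44 was at 4.99 and the antiviral GTPase Mx1 at 1.49. The oxidative burst and antioxidant list stood below random lists (median -0.33, percentile 0), with 3 of 15 genes lower, the antioxidant genes Nqo1 (-2.01), Gclm (-1.16) and Srxn1.

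The highest brighter genes on the KO array with TNF were Chil1, a chitinase-like protein, at 61.7-fold (log2 5.95), Zfp979 at 57.4-fold (log2 5.84) and Hal, the histidine-degrading enzyme, at 36.5-fold (log2 5.19). They were followed by S100a9, Pianp (3.99), the coagulation factor gene F13a1 (3.03), Rarres2 (2.77) and Stfa2 (2.46). The lowest brighter genes were Akr1e1 (-2.79), Gpr176 (-2.42), Flrt3 (-2.39), Vps16 (-2.19), Mzt1 (-2.01), Nqo1, Pard6g (-1.87) and Cxcl12 (-1.86). Among cytokines, Il1b (1.82) and Il18 (1.41) were higher, and Lif (-2.93) and the macrophage growth factor Csf1 (-1.04) were lower. Tnf (-0.50), Il6 (-0.08), Cxcl1 (0.24) and Cxcl2 (-0.49) were not past the rule.

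Nos2, the inducible nitric oxide synthase, was 3.47-fold higher (log2 1.79) and Arg1, which uses the same substrate, 3.26-fold higher (log2 1.71) in KO macrophages with TNF. The classical and alternative activation lists had medians of 0.51 and 0.44, at percentiles 99.99 and 100. Of 17 chemoattractant receptors, 4 were higher (Cxcr1, at least 2.20, with Cxcr2, Cxcr4 and Ccr6; median 0.40, percentile 99.96). These 4 were also at least 2-fold higher on the WT neutrophil array than on the WT macrophage array without TNF. Among CXC chemokines Cxcl13 was higher (2.08), and Cxcl12, Cxcl5 (-1.20) and Cxcl3 were lower. The median of that list, 0.24 (percentile 98.4), lay inside the random range with quantile normalization and with the intensity trend removed. The granule precursor list (0.60, percentile 99.9), the mast cell and basophil list (0.98, percentile 99.8), the monocyte list (0.56, percentile 99.6) and the macrophage list (0.38, percentile 100, Fcgr1 at 2.14) stood above random lists. Mesothelial and fibroblast markers (-0.84, percentile 0, with Col1a1 at -1.48 and Col1a2 at -1.35), resident peritoneal macrophage markers (-0.66, percentile 0.02, with Gata6 at -1.30 and Vsig4 at -1.14) and cell cycle genes (-0.64, percentile 0, with Top2a at -1.12 and Plk1 at -1.09) stood below them.

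Altogether 1655 genes were higher and 638 lower in KO macrophages with TNF among 23907 tested, so 72.2% of the different genes were higher. That share was 60.9% with quantile normalization. The counts were 474 higher and 580 lower once genes at least 2-fold higher on the WT neutrophil array than on the WT macrophage array without TNF were left out, a setting chosen after seeing the data. With normexp background correction the counts were 585 and 234.

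The KO-minus-WT differences of macrophages without and with TNF were set against each other across genes, which are not independent replicates. Pearson's r was 0.772 and Spearman's rho 0.683 over 21739 genes, and the 2 comparisons share no array. The same 671 genes were higher in both, where independent lists would share 59.9, and 216 were lower in both, against 8.45. The labels give both macrophage arrays of a genotype the same mouse numbers, as they do the neutrophil arrays, so these may come from the same mice, which the numbers for independent lists leave out.

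**Figure D3:**
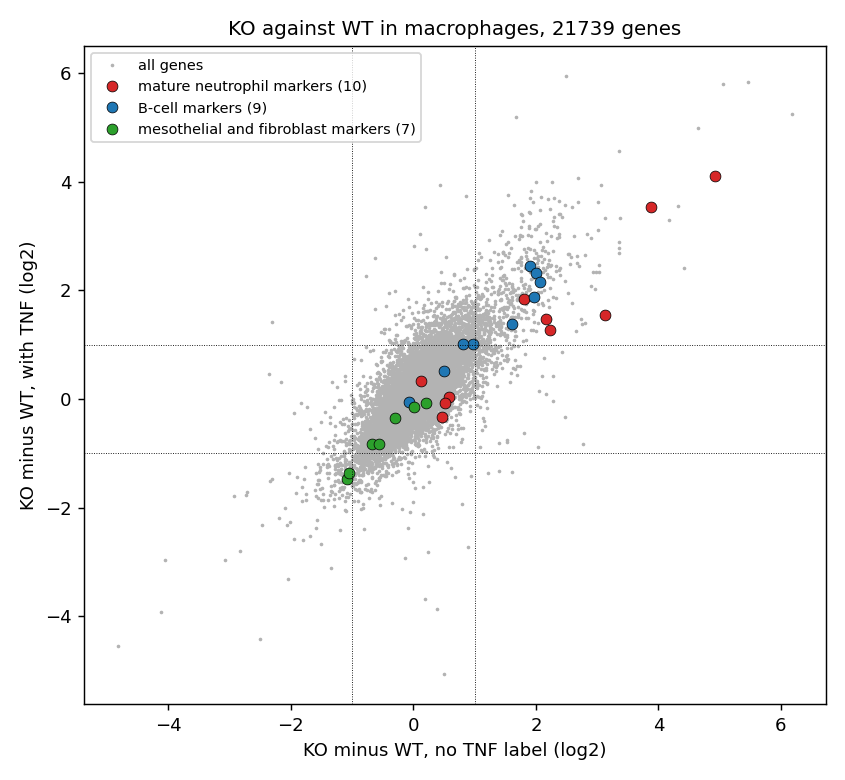
Log2 difference, KO minus WT, of 21739 genes in macrophages without the TNF label (horizontal axis) and with TNF (vertical axis), 1 point per gene, with mature neutrophil markers in red, B-cell markers in blue and mesothelial and fibroblast markers in green. Dotted lines mark a 2-fold difference, and S100a9 lies at 4.92 and 4.10.

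In splenic neutrophils, the receptors for neutrophil-attracting chemokines were higher on the KO array. Cxcr1 was 8.83-fold higher (log2 3.14), the largest increase among brighter genes in this comparison, and Cxcr2 was at 1.63. Of 16 chemoattractant receptors, 5 were higher (Cxcr1, Cxcr2, Ccr1, Ltb4r1 and Ptafr) and Ccr3 was lower (-1.15), with a median of 0.70 and percentile 100. Of 11 mature neutrophil markers, 3 were higher: Mxd1 (1.53), Cxcr2 and Trem3 (median 0.54, percentile 100). The CC chemokines Ccl4 (2.41) and Ccl3 (1.45) and the CXC chemokines Cxcl1 (1.26) and Cxcl12 (1.27) were higher, Ccl24 (-2.68), Ccl2 (-1.04) and Cxcl9 (-1.19) were lower, and the lists' medians were 0.60 and 0.57, at percentiles 99.98 and 100.

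Markers of other blood cells moved with genotype in the neutrophil preparation. Erythroid genes were higher on the KO array, with 6 of 7 past the rule, among them the haemoglobin chaperone Ahsp (2.00) and the erythroid regulator Klf1 (at least 2.61; median 1.68, percentile 100), and Epor, the erythropoietin receptor, lower (-1.04). Plasma cell genes were lower, with 4 of 5 past the rule, Tnfrsf17 at -3.02 and Sdc1 at -2.28 (median -1.71, percentile 0.01). Macrophage genes were lower too, with 7 of 14 past the rule, including Adgre1 (-1.39) and C1qa (-1.29; median -0.98, percentile 0). Eosinophil markers had Prg2 (-4.05), Ear2 (-1.38) and Ccr3 lower and Siglecf higher (1.57; median -1.15, percentile 0.05). Resident macrophage markers had a median of -0.81 (percentile 0.1), with Cd5l at -2.72 and Vsig4 lower by at least 2.94 on the log2 scale (-2.94). Platelet markers had a median of 0.62 (percentile 99.9) with 0 of 6 past the rule. B-cell markers (0.04, percentile 80.8) and T-cell markers (-0.15, percentile 16.1) were not apart from random lists, although Cd3d was higher (2.71) and Cd28 (-2.04) and Cd8a (-1.28) were lower.

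The other brighter genes with the largest increases in KO neutrophils were Camkk1 (2.87), Crispld2 (2.75), Cd3d, the protease Ctse (2.62), Sntb2 (2.52), Fmr1nb (2.51) and the coagulation factor F5 (2.49). The largest decreases among brighter genes were those of Prg2, Adamdec1 (-3.15), Tnfrsf17, Gdf15 (-2.99), Rgcc (-2.95), Tnfsfm13 (-2.92), Slc27a1 (-2.77) and Cd5l. The IL-6 and STAT signalling list had a median of 0.42 (percentile 99.99), with the feedback inhibitor Socs3 past the rule (1.12). Il1rn, the IL-1 receptor antagonist, was higher (1.25) as were the granule proteins Mmp8 (1.21) and Lcn2 (1.14). Cxcl2 (0.88), Tnf (0.84) and Il1b (0.48) were not past the rule, and Il6 was not well above background on either neutrophil array. The lipid and cholesterol list had 5 of 18 genes lower, among them Nr1h3 and Apoe (median -0.38, percentile 0.03), and the cell cycle list had a median of -0.45 (percentile 0). Among 23970 genes tested, 877 were higher and 1135 lower, with normexp background correction 302 and 515, and with no filter on dim probes 2147 and 2066.

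TNF was compared with no TNF label within each genotype, where time in culture may differ too. In both genotypes 11 of 21 NF-kB and TNF signalling genes rose, the same 11 genes, among them Traf1 (2.87 in WT and 2.93 in KO) and the inhibitor Nfkbie (2.91 and 2.80). The medians of this list were 1.47 and 1.38, both at percentile 100. The protease inhibitor Cst7 rose 124-fold in WT and 47.7-fold in KO macrophages, and the chemokine Cxcl3 103-fold and 40.4-fold. Clec4e, a receptor for mycobacterial lipid (5.60 and 4.81), Acod1, which makes itaconate (5.40 and 4.39), and Clmp (5.34 and 5.14) followed on the log2 scale. The formyl peptide receptor genes Fpr-rs6 (5.01) and Fpr2 (4.93), which are similar in sequence, and Wfdc21 (4.81) completed the 8 highest brighter genes in WT, and the arginine transporter Slc7a2 (5.11), Csta2 (4.67) and Gpr84 (4.48) those in KO. Il1b rose by 3.84 and 4.11, Cxcl2 by 3.42 and 1.77, and Tnf by 2.22 and 1.63. Cxcl1 rose in WT (1.03) and was at 0.41 in KO, not past the rule, and Il6 was at 0.27 and 0.53, not past the rule in either.

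Genes that fell with TNF included Nxpe5 (-5.28 in WT and -5.25 in KO), Mamdc2 (-4.05 and -4.46), the monocyte chemokine receptor Ccr2 (-3.73 and -3.64), the complement gene C1qb (-3.53 and -3.28) and the mannose receptor Mrc1 (-2.11 and -2.19). The IgG receptor genes Fcgr1 (-4.11) and Fcgr4 (-4.01) and the receptor gene Sirpb1b (-3.65), from a family of near copies, were among the 8 lowest brighter genes in WT, and Ifitm6 (-4.25), Bex1 (-4.16), Plppr3 (-3.98) and Ednrb (-3.84) among those in KO. Cbr2 (-3.50 and -4.20) and the lysosomal transporter Slc46a3 (-3.65 and -3.98) fell in both. The inflammatory cytokine list had 9 of 16 genes higher in WT and 7 in KO (medians 1.17 and 0.82, percentiles 100 and 99.99). The CC chemokines Ccl22 (3.95 in WT and at least 3.88 in KO) and Ccl17 (3.46 and 4.03) rose. Among alternative activation genes, Arg1, Mrc1, Clec10a and Stab1 were lower and Egr2 higher in WT. In KO, Mrc1, Clec10a, Cd163, Ccl24 and Stab1 were lower. The classical activation list stood above random lists in both genotypes (medians 0.60 and 0.91), and the resident peritoneal macrophage markers stood below them (-1.03 and -1.26). Mesothelial and fibroblast markers (-0.69 and -0.84, both at percentile 0.01) and B-cell markers (-0.48 and -0.32, percentiles 1.08 and 1.64) also stood below, although B-cell markers in KO did not with normexp background correction. Dendritic cell markers (0.48 and 0.76, in KO not apart with the median over all probes of a gene) and eosinophil markers (0.57 and 0.66) stood above. Mature neutrophil markers were at 0.67 (percentile 100) in WT and 0.00 (percentile 27.0) in KO, and erythroid markers at -0.81 (percentile 5.52) and -1.56 (percentile 0.11). Counts were 1084 higher and 1130 lower of 24626 genes in WT, and 1065 higher and 892 lower of 24048 in KO. With normexp background correction they were 622 and 449 in WT and 570 and 393 in KO.

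The TNF differences of WT and KO macrophages had Pearson's r of 0.820 and Spearman's rho of 0.705 across 21739 genes, and a major axis slope of 0.946. They shared 659 higher genes, against 40.3 for independent lists, and 584 lower genes, against 40.0.

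**Figure D4:**
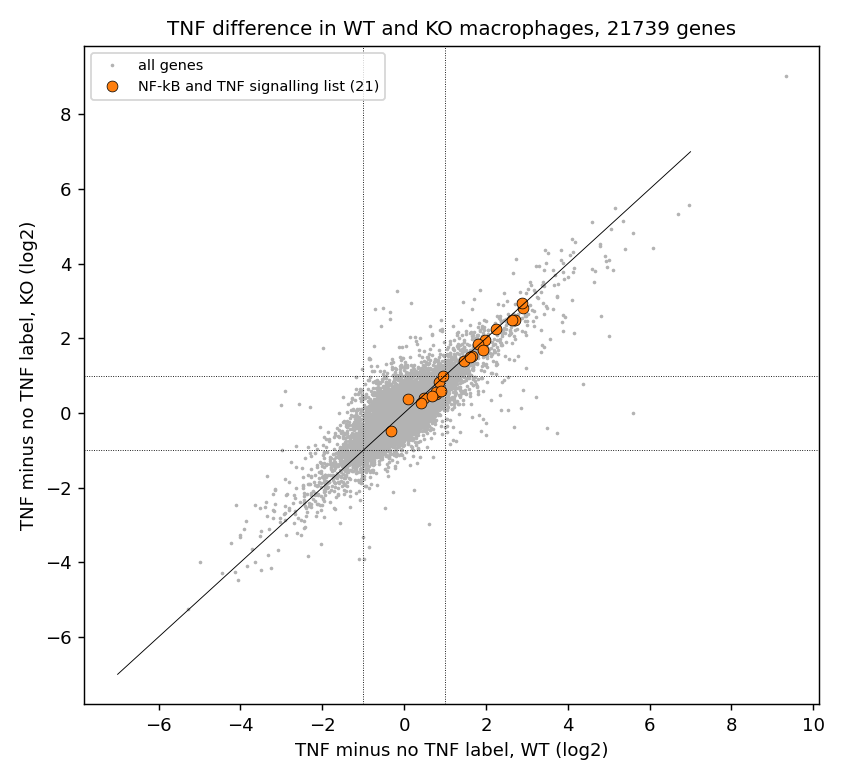
Log2 difference, TNF minus no TNF label, of 21739 genes in WT macrophages (horizontal axis) and KO macrophages (vertical axis), 1 point per gene, with the 21 NF-kB and TNF signalling genes in orange and the line of equal differences in black. Dotted lines mark a 2-fold difference, and Traf1 lies at 2.87 and 2.93.

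The TNF difference itself was then compared between genotypes, as KO minus WT, over 21739 genes well above background on all 4 macrophage arrays. Chil1 (3.45) and Hal (3.52) had a more positive TNF difference in KO, followed by Pianp (1.99), Htr2b (1.75), the sialic acid receptor Siglec1 (1.68), Fcgr1 (1.65), F13a1 (1.61) and Chac1 (1.60). Nos2 (1.32) and Arg1 (1.02) also passed the rule. The CXC chemokine list had a more negative TNF difference in KO, with Cxcl2 (-1.66), Cxcl3 (-1.36) and Ppbp (-1.31) past the rule among 12 (median -0.43, percentile 0). Cxcl2 was past the rule as higher on the KO array without TNF and not past it with TNF, so its value also reflects the level without TNF. Cxcl2 and Ppbp were also higher, and Cxcl3 lower, in WT neutrophils than in WT macrophages without TNF. Lif, a cytokine of the IL-6 family, was at -2.79. The haemoglobin genes Hba-a1 (-2.73) and Hba-a2 (-2.32), whose near-identical sequences let a probe pick up the RNA of both, were also more negative. So were Wfdc21 (-2.21), the lipoxygenase Alox15 (-1.96), Mmp9 (-1.70), Stfa2l1 (-1.58), Adora2b (-1.57) and Nqo1 (-1.18).

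Interferon-stimulated genes had a median of 0.35 in this difference of differences (percentile 100) with 0 of 22 past the rule. Mature neutrophil markers, which were higher on both KO macrophage arrays, had a median of -0.64 (percentile 0), and the NF-kB and TNF signalling list one of -0.11 (percentile 7.1). In all, 325 genes were more positive and 135 more negative in KO, so 70.7% were more positive. That share was 53.2% with normexp background correction, where the counts were 66 and 58, and 60.0% with the intensity trend removed.

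WT neutrophils were compared with WT macrophages without the TNF label to show what the preparations held. Mature neutrophil markers were higher in neutrophils for 10 of 11 genes (median 5.02, percentile 100), with S100a9 at 7.63, Cxcr2 at 6.53 and Cxcr1 at 4.35. B-cell markers were higher for 10 of 10 (median 6.63), erythroid markers for 6 of 6 (6.03) and platelet markers for 5 of 6 (5.13), all at percentile 100. A higher signal on this array therefore does not by itself mark a gene as one of neutrophils. The brighter genes with the largest increases were the antibody chain linker Jchain (10.29), the granule genes Camp (9.80) and Ltf (9.13), Hcar2 (8.78), Dtx1 (8.61), Cd69 (8.61), Hbb-bt (8.56) and Cr2 (7.85). Immediate early and stress genes were higher for 11 of 13, with Fosb at 7.51 and Hspa1a at 7.50 (median 3.35, percentile 100).

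Macrophage markers were lower in the neutrophil array for 9 of 14 genes (median -1.42), with Msr1 at -7.95 and Lyz2 at -4.72, and mesothelial and fibroblast markers for 8 of 8 (median -7.78), both at percentile 0. The largest decreases among brighter genes were those of Gpnmb (-12.31), Emp1 (-10.64), the lipid receptor Trem2 (-10.60), Fn1 (-10.07), Pdpn (-9.66), Timp1 (-9.02), Fam20c (-8.91) and Ctsk (-8.66). Antigen presentation genes were higher for 10 of 14, such as Ciita (4.23) and Cd74 (3.78; median 2.32, percentile 100). Steap4 was at -0.76, not past the rule. Of 25566 genes tested, 6625 were higher and 4487 lower. The median over all genes was 0.16 and became 0.05 with quantile normalization, a shift not shown gene by gene.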

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

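No test was run in this part, since each group holds 1 array, and the genes were picked after their values were seen because they passed the rule of size in opposite directions in a pair of conditions. There are 11 such genes among those named, and none of these differences between conditions was tested.

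The protease Adamdec1 was higher on the KO array in macrophages with TNF (log2 5.39) and lower in neutrophils (-3.15), a gap of 8.53. The eosinophil attractant Ccl24 was at 1.69 in KO macrophages without TNF and at -2.68 in KO neutrophils, a gap of 4.37. Cxcl12, which holds blood cells in the marrow, went the other way, at -1.86 in macrophages with TNF and 1.27 in neutrophils, a gap of 3.13. Csf1 was at -1.04 in macrophages with TNF and 1.23 in neutrophils, a gap of 2.27. Fcgr1 was at 2.14 and -1.24 in these conditions, a gap of 3.38, and the lipid carrier gene Apoe at 1.03 and -1.10, a gap of 2.13.

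Chac1 was at 1.85 in macrophages with TNF and -1.91 in neutrophils, a gap of 3.75, and the eosinophil gene Ear2 at 1.27 and -1.38, a gap of 2.64. Flrt3 was at -2.39 and 1.38, a gap of 3.76, and the fatty acid receptor gene Gpr84 at -1.15 and 1.03, a gap of 2.18. The haemoglobin gene Hba-a1 differed between macrophages without TNF, at 1.40, and with TNF, at -1.33, a gap of 2.73. The neutrophil preparations also differed in macrophage and eosinophil markers, with medians of -0.98 and -1.15.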

How the results depend on the processing

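The alternative without genes high in the neutrophil array was chosen after seeing the data, and the other 7 beforehand. No paired analysis was possible because each group holds 1 array, as far as a condition taken alone goes, and a model across conditions with the condition as a block could have been fitted but was not. Of 480 results past the rule, each a named gene in 1 comparison, 366 stayed past it in the same direction under all 7, 114 changed under some and 2 reversed. Of 119 results of a list apart from random lists in 1 comparison, 101 stayed apart, 18 changed under some and 2 reversed. The 4 correlations across genes, from 0.116 to 0.820, and the slope of 0.946 moved by less than 0.1 under each of the 7. Scaling to the median of detected probes and the changes to the filter on dim probes cannot alter these values. By construction they also leave the position of a list in a single comparison of arrays as it was. Only the remaining settings could show a change there. The reversals all came with the median over all probes of a gene. They were Adam22 with TNF in WT (-0.23), Tpsb2 in neutrophils against macrophages (-1.05), and, as median less that of random lists, the iron and STEAP list in macrophages without TNF (-0.0210) and the CXC chemokine list with TNF in KO (-0.11). Their cause was not tested.

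With normexp background correction, counts of higher and lower genes for KO against WT were 332 and 106 in macrophages without TNF, 585 and 234 with TNF, and 302 and 515 in neutrophils. They were 622 and 449 for TNF in WT, 570 and 393 in KO, 66 and 58 for the difference between these, and 26 and 14 for all 3 conditions. Steap4 with TNF was then at -0.32 and no longer past the rule. The cause was not tested. With no filter on dim probes, which adds dim genes by construction, the KO against WT counts were 2301 and 1054 without TNF, 3128 and 1264 with TNF, and 2147 and 2066 in neutrophils. They were 1983 and 2291 for TNF in WT, 1995 and 1742 in KO, 2377 and 1482 for the difference between these, and 13591 higher for neutrophils against macrophages. With probes required to be well above background on all arrays of a comparison, Steap4 with TNF (-1.59) dropped out by construction, and 22 genes were lower in all 3 conditions. Without genes high in the neutrophil array, 305 genes were higher in KO macrophages without TNF and 474 with TNF, fewer by construction. Signal over background limited the dim genes, since between 37.8% and 43.4% of probes were not well above it.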

Other observations

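Of the tests given here, that of the neutrophil markers over all 7 alternatives and that of Cxcr1 and Cxcr2 over these alternatives were set out before their results were seen, and all others were chosen only after.

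Genes that differed the same way between KO and WT in macrophages without TNF, with TNF and in neutrophils numbered 89 higher and 40 lower, where independent lists would give 20.2 and 4.80. These counts were 26 and 14 with normexp background correction, and 22 were lower with signal well above background required on all arrays. Zfp979 was at log2 5.45, 5.84 and 7.16, Atp6v0e2, a proton pump subunit, at 5.06, 5.80 and 3.78, and the interferon-induced gene Ifi44 at 4.65, 4.99 and 1.56. Among the lower ones, Rab6b, a Golgi transport gene, was at -4.13, -3.93 and -4.61, Mrpl35, of the mitochondrial ribosome, at -3.81, -3.83 and -2.85, and Akr1e1 at -2.83, -2.79 and -2.94. These 6 genes were chosen after their values were seen. The correlation of the neutrophil differences with those of macrophages was 0.116 without and 0.137 with TNF across genes, and 103 genes higher in both macrophage comparisons were lower in neutrophils, against 23.4 for independent lists.

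In KO against WT macrophages without TNF, apoptosis (0.12, percentile 89.7), adhesion and matrix degradation (0.06, percentile 45.0), lipid and cholesterol (0.01, percentile 3.71), immediate early and stress (0.15, percentile 90.3) and housekeeping genes (0.11, percentile 51.2) were not apart from random lists, nor were IL-6 and STAT signalling genes (0.04, percentile 42.7). In the same macrophages without TNF, the iron and STEAP list stood at percentile 97.8 (0.19), with Lcn2 past the rule, lay inside the random range with quantile normalization and with the intensity trend removed, and went below the median of random lists with the median over all probes of a gene (-0.0210). The iron and STEAP list was not apart with TNF (0.18, percentile 92.9), and stood below random lists in KO neutrophils (-0.23, percentile 2.34), where it lay inside the random range with normexp and with the intensity trend removed. Marker lists of NK cells (-0.01, percentile 33.2), dendritic cells (-0.03, percentile 17.8), plasma cells (0.03, percentile 32.4), eosinophils (-0.06, percentile 21.5), erythroid cells (0.51, percentile 94.8) and platelets (0.63, percentile 94.2) were not apart without TNF either. With TNF, IL-6 and STAT signalling genes stood above random lists (0.26, percentile 99.6), and lipid and cholesterol (-0.29, percentile 0.01) and adhesion and matrix degradation genes (-0.14, percentile 1.63) below them. Among the genes past the rule in KO macrophages with TNF, lincRNA probes made up 321 of 1655 higher and 42 of 638 lower. They were 16194 of all 55680 probes, and their share of the tested genes was not counted, so no excess is shown.

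The mature neutrophil markers were higher on both KO macrophage arrays. A smaller share of macrophages, raising all other cell types alike, is argued against by mesothelial and fibroblast markers (median at most -0.62). These cells may themselves differ in number between single preparations, so a smaller share is not excluded, although general macrophage markers stood above random lists in both comparisons. More neutrophil RNA in the KO preparations may account for the pattern. Shares were taken only from markers at least 16-fold higher on the WT neutrophil array than on both WT macrophage arrays. This filter, set after the data were seen, picks markers with little WT macrophage signal. The signal added, as a percent of that of the WT neutrophil array, had medians of 7.74% and 4.60% over 5 such markers and quartiles within 2.46-fold. Csf3r, Retnlg, Mxd1 and Trem3 were outside these and not past the rule on either KO macrophage array. Itgb2l, among these 5, gained only 0.0565% without TNF, where it was not well above background on the KO array. RNA with the makeup of the splenic preparation is argued against by granule precursor genes, whose median was at most 0.882%, although Lcn2 gained 11.1% and 24.0%. These were 4 genes, of which Ngp was not well above background on either KO macrophage array. B-cell markers gained medians of 2.04% without and 1.59% with TNF over 9 genes, of which Pax5 was not well above background on either KO macrophage array. Scaling between arrays is argued against only for the 3 settings that change it alone, under which the median was at least 1.43. None of them scaled to the spike-ins, whose mean log2 differences before scaling were 0.27 and 0.42, higher on the KO arrays. The 75th percentile signals used for scaling were lower on the KO arrays, 410 against 490 without TNF and 338 against 432 with TNF. Scaling to the spike-ins would therefore lower the KO values reported here by more than 0.27 and 0.42. It was not run, so its part cannot be told apart. With normexp and TNF the median dropped to 0.925, under the bound of 1 set beforehand. By the rule set beforehand, such a drop goes with the processing, background correction included, as a cause. The list stayed at percentile 100 under all 7 alternatives, some of which cannot change it. That percentile was not part of the rule, so it does not undo this outcome. A part of the background correction is therefore not argued against, and expression by the KO macrophages themselves stays open and untested.

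Genes lower in all 3 conditions were 8.34 times as many as independent lists give. That was 3.13 times the same ratio of genes going the opposite way in neutrophils, which argues against chance overlap. For the higher genes the ratio was 4.41, also above that of independent lists, but only 1.00 times that of the opposite way. The overlap of the higher genes therefore does not show a shared direction. Both numbers leave out that the conditions may share mice. Donor DNA kept beside Steap4 is argued against as the source of most of these genes, as 0 of the 125 with a position lay within 20 Mb of it. Since only 0.873 would by chance, this count cannot tell whether such DNA was kept there. Segments of another strain elsewhere are a candidate explanation, because 44 of the 82 with a symbol and position had another within 5 Mb, against a median of 31 and a range of 20 to 42 in random sets. The higher genes alone (23 of 56, range 8 to 24) and the lower ones alone (6 of 26, range 0 to 9) lay inside their ranges, and co-expressed neighbours such as Cxcr1, Cxcr2 and Rufy4 count too. An effect of the deletion stays open and untested. So does RNA of cells like those in the splenic preparation for 33 of 56 higher genes, also higher on the WT neutrophil than the WT macrophage array. Of the lower genes, 2 of 26 were, and among all 25566 genes tested 6625 were. That preparation also had higher B-cell, erythroid and platelet markers, so RNA of neutrophils cannot be told apart from theirs.

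Cxcr1 and Cxcr2 were higher on the KO neutrophil array, at 3.14 and 1.63. A larger share of neutrophils as the whole account is argued against, since 10 other mature neutrophil markers had a median of 0.44 with an SD of 0.53. As a part of it, a larger share cannot be told apart. The mature neutrophil list stood above random lists, and macrophage, plasma cell and eosinophil markers stood below them, although erythroid and platelet markers stood above. Scaling by the settings used is argued against, with 1.56 the lowest value of either gene over the 7 alternatives. None of these scaled to the spike-ins, whose mean log2 difference before scaling was 0.37. Such scaling would lower the reported values by more than that, as the 75th percentile signal was 224 in KO and 231 in WT neutrophils. A regional difference on chromosome 1 cannot be told apart, because 1 of 17 other measured genes within 0.5 Mb, the neighbour Rufy4, was also at least 2-fold higher and the bounds set for this test left such a value undecided. An effect of the KO genotype on these receptors may also stand behind the difference, a hypothesis that 1 array per group leaves untested.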
